A study of Mus musculus with 18 samples.

How the data were processed

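The study followed secondary reprogramming, in which fibroblasts that already carry doxycycline-inducible copies of the factors Oct4, Sox2, Klf4 and c-Myc are turned into induced pluripotent stem cells (iPSC) by adding the drug. Per the labels' protocols, the mouse embryonic fibroblasts came from embryos at embryonic day 13.5 made wholly from iPSC by tetraploid complementation, carried an Oct4-GFP reporter and the Rosa26-M2rtTA transactivator, and were used at passage 4. The day 0 cells grew in a fibroblast medium. The cells of days 1 to 15 were in a medium for embryonic stem cells with doxycycline (1 µg/ml) and vitamin C (50 µg/ml), so that every comparison with day 0 holds the change of medium and vitamin C as well as the factors. Both additives were then removed and the surviving cells were collected 3 days later as day 18. The iPSC line was kept in the stem cell medium with inhibitors of Gsk3 and Mek (2i), with or without feeder cells, and the labels do not say which of these conditions the iPSC arrays had.

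Total RNA was hybridised to 18 Affymetrix arrays, 2 for each of 9 groups. The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays against each other and summarises the probes of a probe set. Its version, the chip definition and the genome build are not given in the sources used here. Quantile normalization gives the arrays nearly the same distribution of values, so a change shared by most genes would not be visible. The table held 29643 probe sets named by RefSeq accession, with log2 values from 2.12 to 13.72 and array medians from 6.69 to 6.89.

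Accessions were matched without their versions to a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of the probe sets, 27260 matched 1 symbol, 0 matched several and 2383 matched none. This gave 20233 genes, of which 3982 had over 1 probe set. The probe set with the highest mean over all arrays stood for the gene. The values of 2623 probe sets equalled those of an earlier probe set on all arrays, and 30 genes could not be separated from another gene for that reason. No gene had probe sets called in opposite directions between iPSC and day 0 (0 genes). As a measure of background, the 1075 olfactory receptor genes, mostly silent outside the olfactory epithelium, had a median level of 3.56 and a 95th percentile of 5.32 on the log2 scale, and 4897 genes stayed under that percentile in all 9 groups. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.0976.

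Genes were tested with limma (version 3.58.1, R 4.3.3), by a linear model with a mean for each of the 9 groups fitted to all 18 arrays, which share 1 estimate of the spread per gene with 9 residual degrees of freedom and a prior of 4.25. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 within the comparison and the log2 difference was at least 1 in size. The SE of a log2 difference is that of this model. Each day and iPSC were compared with day 0, and each group with the one sampled before it. A gene counted as transiently higher or lower if on at least 1 of days 1 to 15 it was called in the same direction against both day 0 and iPSC. The half-change day was the earliest sampled day on which the group mean had covered 0.5 of the difference between day 0 and iPSC. The share of the distance was each array's projection, over all genes, on the line from the day 0 mean to the iPSC mean. Gene lists were tested with limma's camera, which asks whether the genes of a list moved more than other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 32 lists in each comparison. The same test with a correlation estimated from the data was an alternative. In a simulation of 20233 genes with the means and spread of these arrays, 100% of genes changed by 1.5 log2 between day 1 and day 0 were recovered. In it 1 unchanged gene was called. The noise was independent for each gene and array, so correlated genes and deviating arrays were not covered.

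Gene lists, comparisons, tests and most alternatives were chosen before the data were examined. So was the rule for naming genes: the 10 called genes with the largest rise and the 10 with the largest fall in the comparisons of day 1 and iPSC with day 0, of day 18 with day 15 and of iPSC with day 18, with no overlap between the arrays of the groups. For the other intervals it took 5 and 5, for transient genes 10 and 10, for genes that moved at induction and back at withdrawal the 10 with the largest smaller change, and for each list the 4 members that moved most. A fixed set of reprogramming, pluripotency, imprinted and sex-linked genes was always in the rule. Predicted genes and families such as olfactory receptors were counted and not named, and members were left out for length. For 1 gene picked by this rule the result is not reported. Alternatives were another quantile normalization, equal array medians, a filter on dim genes, the mean of a gene's probe sets, all probe sets, a trended and robust variance model, the replicate number as a block, other fold limits, fits of only the groups compared, and leaving out each array in turn. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Groups of 2 allow no test for single deviating arrays, and an exact permutation test of 2 against 2 cannot pass a threshold of 0.05. Figures were drawn with matplotlib 3.10.9.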

Results

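Gene expression was measured on 18 arrays from mouse fibroblasts before induction of the 4 reprogramming factors (day 0), cells on days 1, 3, 5, 7, 11 and 15 of induction, cells 3 days after the removal of doxycycline and vitamin C (day 18) and an established iPSC line, with 2 arrays in each of the 9 groups. Values are log2 levels of 20233 genes. The arrays of a group correlated over genes at r = 0.997 to 0.998, except those of day 18, at 0.993. There 264 genes differed by over 2-fold between the arrays, against 5 to 16 in the other groups. The SD over genes of the difference between arrays was 0.278 on day 18 and 0.134 to 0.174 in the others. The model pools 1 spread per gene over all groups. Its SEs and p-values in comparisons with day 18 are therefore too small for genes that varied more there. Sex-linked transcripts differed between the groups, with the Y-linked gene Eif2s3y at log2 4.24 ± 0.13 (SD, n = 2) on day 0 and 8.53 ± 0.01 on day 18. Xist, which coats the inactive X chromosome, stood at 5.01 ± 0.13 on day 0 and 8.53 ± 0.10 in iPSC. The day 0 levels of both genes lay under the background of 5.32. Whether all groups came from the same cells was not tested, and each comparison between groups holds any such difference.

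The course was fastest at its start. Day 1 arrays lay 42.1% ± 0.23 (SD, n = 2) of the way from the fibroblasts to iPSC, day 3 arrays at 54.3% ± 0.22, day 7 at 61.8% ± 0.50, day 11 at 71.8% ± 0.05 and day 15 at 76.7% ± 0.06. Day 18 stood at 83.8% ± 8.13, from arrays at 78.0% and 89.5%. Log2 differences of genes whose lower level lay under the background of 5.32 are lower bounds, which among the list members named holds for Ifit1, Ifit3, Il6, Dsp and Cdh1, for Krt14, Rhox9, Ehf, Dazl and Dnmt3l, and for Stra8, Tcl1 and Plac1. In limma's F test with Benjamini-Hochberg adjustment and no minimum fold change, 15935 genes (78.8%) differed over the 9 groups. The test included the 4897 genes whose means lay under the background of 5.32 in all 9 groups, and the 15935 include some of these. Its p-values measure only the spread between these arrays, so small shifts can pass. With the fold limit, 7336 genes were called in at least 1 comparison with day 0. Against day 0, 2865 genes were called on day 1, 3566 on day 3, 3894 on day 5, 4045 on day 7, 3951 on day 11, 3814 on day 15, 3543 on day 18 and 4019 in iPSC. Between neighbouring samples it was 614 from day 1 to day 3, 233 to day 5, 207 to day 7, 618 to day 11, 386 to day 15, 1769 to day 18 and 892 from there to iPSC. The median of all genes shifted by 0.11 on day 3 and 0.13 on day 5 against day 0.

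**Figure D1:**
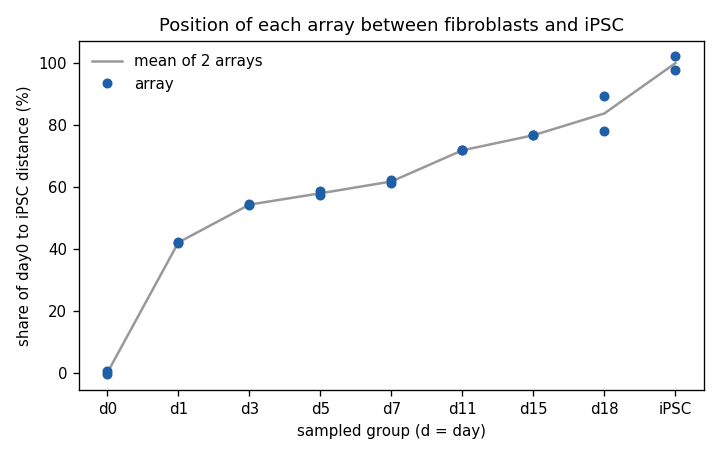
Each point is 1 array, placed by its projection on the line from the day 0 mean (0%) to the iPSC mean (100%) over 20233 genes, and the line joins the means of the 2 arrays. Day 1 lies at 42.1%, and the arrays of day 18 lie apart at 78.0% and 89.5%.

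**Figure D2:**
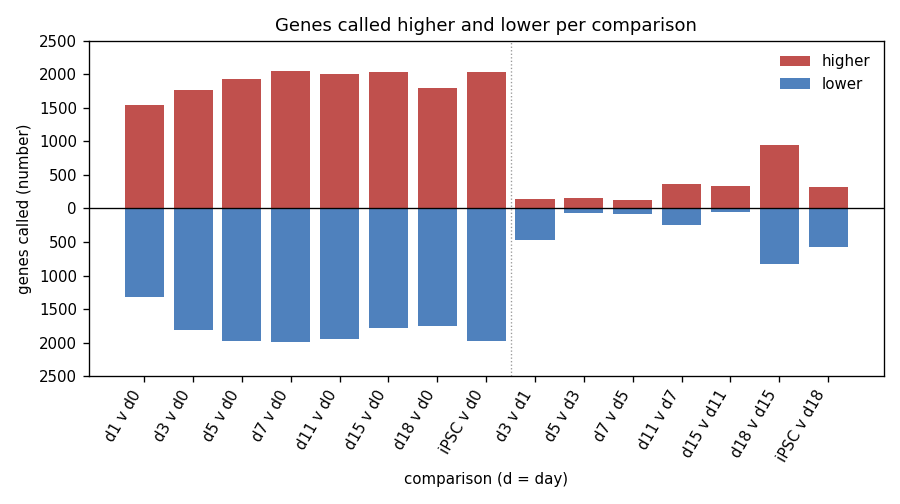
Bars above 0 count genes called higher and bars below 0 genes called lower in each comparison (limma, adjusted p under 0.05 and a log2 difference of at least 1). Comparisons with day 0 stand left of the dotted line and those between neighbouring samples right of it, where day 18 against day 15 has the most calls, 945 higher and 824 lower.

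The comparison of day 1 with day 0 asked what the first day of induction changed. Fibroblast and inflammatory genes fell and cell cycle genes rose, calls that were all lost when the correlation between genes was estimated. The fibroblast and inflammatory lists then had adjusted p = 0.564 and 0.0686 with an estimated correlation, and those of DNA replication and mitosis 0.0686 and 0.163. The largest measured rises were those of the adhesion gene Ceacam1, by 6.01 ± 0.10 (SE) on the log2 scale, and of Pou5f1, which encodes Oct4, by 5.53 ± 0.07. They were followed by Dynap (4.44), the sialomucin gene Podxl (3.95), the protease gene Tmprss11b (3.72), Elmod1 (3.60), the imprinted gene Phlda2 (3.56), Serpinb9b (3.52), the cornified envelope gene Sprr2b (3.44) and the amino acid transporter gene Slc6a15 (3.42). The largest falls were those of the matrix genes Lum (-5.90 ± 0.15) and Abi3bp (-5.81), the opioid precursor gene Penk (-5.50), Lrrc17 (-5.46), the collagenase gene Mmp13 (-4.97), the chemokine gene Cxcl5 (-4.89), Igfbp5 (-4.73), the proteoglycan gene Aspn (-4.72), the collagen receptor gene Itga11 (-4.64) and Medag (-4.54). The lower of the 2 levels lay under the background of 5.32 for 6 of these 10 rises, Ceacam1 and Pou5f1 among them, and for 5 of the 10 falls, so these differences are lower bounds. In all, 1541 genes were higher and 1324 lower, and 1337 and 1397 after another quantile normalization. The adjusted p of limma with Benjamini-Hochberg was 3.72e-15 for Pou5f1 and 7.50e-06 for Igfbp5.

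Of the 30 fibroblast genes 17 fell on day 1, 0 rose and 13 were not called, adjusted over the list alone 18 fell. The receptor genes Pdgfrb and Pdgfra stood at -3.77 and -3.69. The list had camera adjusted p = 3.97e-10, and adjusted p = 0.564 with an estimated correlation. Of 25 mesenchymal regulators and TGF-beta targets 8 fell, adjusted over the list alone 8, with Tgfbi at -4.51 and Snai1, a repressor of E-cadherin, at -1.65 (adjusted p = 7.36e-05, and adjusted p = 0.640 with an estimated correlation). Interferon response genes fell in 11 of 29 cases, adjusted over the list alone 11, with Ifit3 at -3.20 and Ifit1 at -3.05 (adjusted p = 9.71e-05, and adjusted p = 0.582 with an estimated correlation). Inflammatory genes fell in 12 of 28 cases, adjusted over the list alone 12, with Il6 at -3.51 (adjusted p = 2.97e-05, and adjusted p = 0.0686 with an estimated correlation). DNA replication genes rose in 26 of 29 cases, adjusted over the list alone 26, led by Mcm10 at 2.35 (adjusted p = 9.38e-17, and adjusted p = 0.0686 with an estimated correlation). Mitosis genes rose in 23 of 29, adjusted over the list alone 23, led by the kinase gene Nek2 at 2.22 (adjusted p = 2.04e-15, and adjusted p = 0.163 with an estimated correlation). The epithelial list was not called on day 1 (adjusted p = 0.0993), although Dsp, which encodes desmoplakin, stood at 2.88. No list was called with an estimated correlation on day 1 or day 3, where the counts were 0 against 10 and 16 with the preset one.

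The comparisons of neighbouring days asked what the intermediate cells expressed. Against day 0 the keratinocyte and epithelial lists were not called on day 1 and were both called on day 3. Of 24 keratinocyte genes 11 were higher on day 3 and 1 lower, adjusted over the list alone 11 and 1 (adjusted p = 0.000263, and adjusted p = 0.171 with an estimated correlation). Of 30 epithelial genes 5 were higher, adjusted over the list alone 5 (adjusted p = 0.00166, and adjusted p = 0.418 with an estimated correlation). From day 1 to day 3 the cornified envelope gene Sprr1b rose by 4.39 ± 0.18 (SE), the basal keratin gene Krt14 by 3.52, the protease inhibitor gene Spink12 by 3.52, Fetub by 3.34 and the keratinocyte gene Krtdap by 3.27. The matrix gene Postn (-2.98), Raet1d (-2.87), the interferon-inducible gene Ifi211 (-2.82), P4ha3 (-2.67) and Clca3a1 (-2.57) fell. From day 3 to day 5 the late cornified envelope genes Lce1a1 and Lce1e rose by 3.41 and 2.93, Necab1 by 3.35, Crct1 by 3.21 and Sox2 by 3.08. From day 5 to day 7 the pluripotency genes Nr0b1 and Nanog rose by 2.81 and 2.60, Tfap2d by 2.73, Nefl by 2.70 and Pllp by 2.31. Spink12 (-3.41) and Spink6 (-2.55) fell in that interval, and so did the Y-linked genes Ddx3y (-3.04) and Uty (-2.98). The keratinocyte list was called on day 5 with 14 of 24 members higher and 1 lower than on day 0, adjusted over the list alone 14 and 1, with Krt14 at 5.09 and Krt17 at 3.96, adjusted p = 2.47e-05, and adjusted p = 0.114 with an estimated correlation.

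Epithelial genes were higher than on day 0 in 14 of 30 cases on day 7 and in 27 on day 11, adjusted over the list alone 14 and 27 (adjusted p = 1.57e-06 and 1.43e-14, and adjusted p = 0.183 and 0.0579 with an estimated correlation). From day 7 to day 11 the splicing regulator gene Esrp1 rose by 3.90 ± 0.11 (SE), Clec2f by 5.09, Cyp2b23 by 4.16, the pluripotency gene Tdgf1 by 3.47 and the tight junction gene Cldn6 by 3.33. In the same interval Rgs6 (-3.72), Sprr1b (-2.94), Vstm2a (-2.86) and Reln (-2.77) fell. From day 11 to day 15, with 336 genes higher and 50 lower, Serpinb9f rose by 4.09, the keratin gene Krt7 by 3.61, Serpinb9e by 3.56, the DNA methylation cofactor gene Dnmt3l by 3.44 and Gpr50 by 3.32. Prg4 (-2.29), Tfap2b (-1.96) and Prrx1 (-1.89) fell. Of the 50 genes that the rule gave for the intervals up to day 15, the lower level was under background for 20. On day 15 all 30 epithelial genes were higher than on day 0, adjusted over the list alone 30, with Dsp at 6.12, Cdh1, which encodes E-cadherin, at 5.84 and the keratin gene Krt8 at 5.62. That list had camera adjusted p = 5.52e-18, and adjusted p = 0.0402 with an estimated correlation. Of 22 trophoblast genes 17 were higher on day 15 and 0 lower, adjusted over the list alone 17, with Krt18 at 5.37 and Rhox9 at 3.57 (adjusted p = 7.72e-08, and adjusted p = 0.0917 with an estimated correlation). Krt8 and Krt18 are in both of these lists. On day 18, 18 trophoblast genes were higher than on day 0 (adjusted p = 9.15e-11, and adjusted p = 0.0602 with an estimated correlation). On day 15, of 24 keratinocyte genes 16 were higher than on day 0 and 1 lower, adjusted over the list alone 16 and 1, with Krt17 at 6.09 and the factor gene Ehf at 4.32 (adjusted p = 1.52e-07, and adjusted p = 0.0402 with an estimated correlation).

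Pluripotency genes came on at different times. Sox2 stood at 5.78 ± 0.23 (SD, n = 2) on day 0, 6.37 ± 0.05 on day 3, 9.45 ± 0.13 on day 5 and 12.30 ± 0.08 in iPSC. Nanog stood at 5.33 ± 0.07 on day 3, 7.10 ± 0.16 on day 5, 9.70 ± 0.05 on day 7 and 12.48 ± 0.07 in iPSC. Esrrb was at 5.37 ± 0.02 on day 7, near the background of 5.32, and at 7.05 ± 0.26 on day 11. Dppa3 stood at 6.62 ± 0.06 on day 15 and 9.13 ± 0.19 on day 18, and Zfp42 at 4.91 ± 0.12 and 6.24 ± 0.00. Cdh1 stood at 7.22 ± 0.02 on day 3 and Epcam, another epithelial surface gene, at 7.33 ± 0.00 on day 7. Thy1 and Col1a1, surface and collagen genes of fibroblasts, were at 6.73 ± 0.12 and 7.96 ± 0.01 on day 15, from 11.40 and 12.32 on day 0. Levels of Pou5f1, Sox2, Klf4 and Myc can include the transgenes, and whether their probes read them was not tested here.

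**Figure D3:**
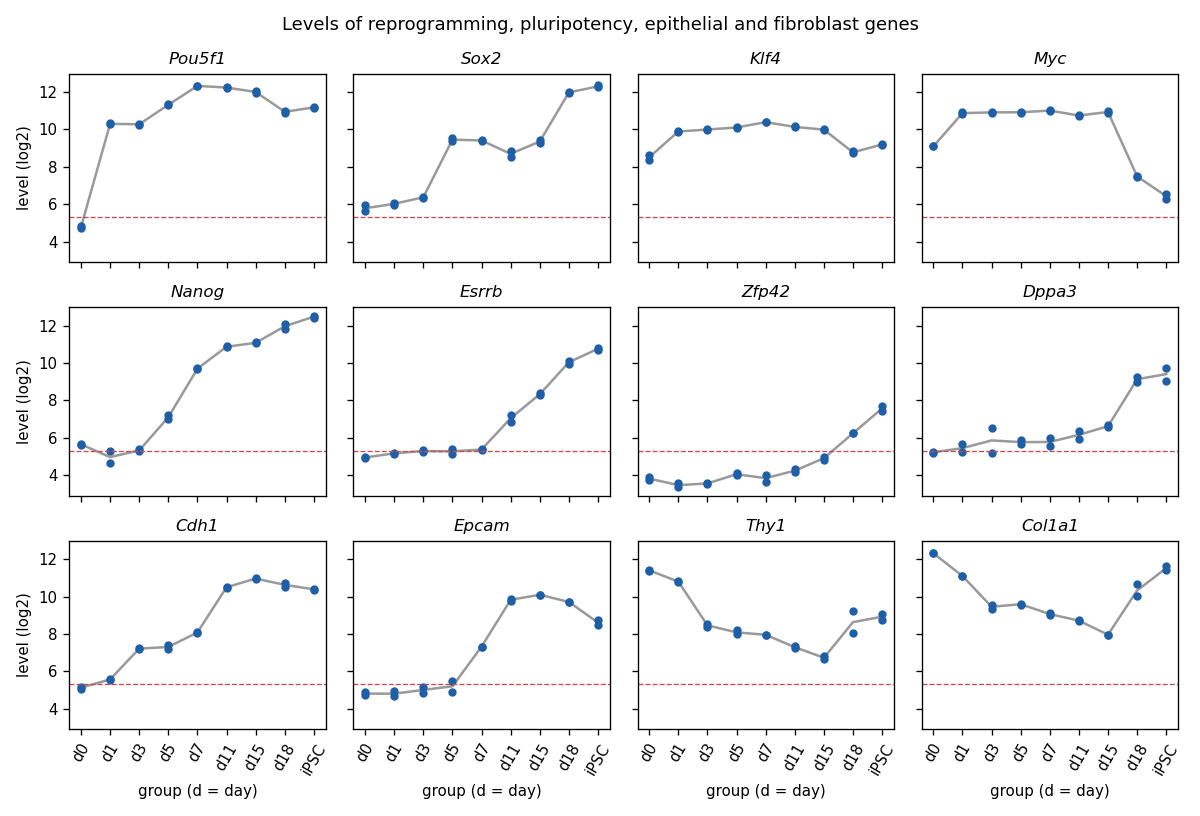
Log2 level of 12 genes in each array (points) and the mean of the 2 arrays (line) in the 9 groups, with the 95th percentile of olfactory receptor genes, 5.32, dashed. Pou5f1 is high from day 1, Sox2 from day 5 and Esrrb from day 11, and Thy1 and Col1a1 are lowest on day 15.

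In iPSC against day 0, the whole distance of the course, pluripotency, germline and cell cycle genes were higher and fibroblast and inflammatory genes lower. The calls of the germline, mitosis and fibroblast lists were lost, with adjusted p = 0.0688, 0.0728 and 0.272 with an estimated correlation. The largest measured rises were those of the pluripotency genes Dppa5a, by 7.92 ± 0.12 (SE), Tdgf1, which encodes a Nodal co-receptor, by 7.67, Nr0b1 by 6.88, Fbxo15 by 6.85, Nanog by 6.82 and Sox2 by 6.52, of the uridine phosphorylase gene Upp1 by 6.66, and of Pou5f1 by 6.41, Bex1 by 6.39 and AU018091 by 6.26. The largest falls were those of the interleukin-33 receptor gene Il1rl1 (-5.77), the lysozyme gene Lyz2 (-5.30), Serpina3n (-5.01), the chemokine genes Cxcl5 (-4.92) and Ppbp (-4.88), the matrix gene Mgp (-4.67), Abi3bp (-4.64), the urea transporter gene Slc14a1 (-4.59), Mmp13 (-4.53) and Igfbp5 (-4.46). The lower level was under background for 8 of these rises and 6 of the falls, which are lower bounds. There were 2038 genes higher and 1981 lower, and 1948 and 2097 after another quantile normalization. Myc was lower in iPSC, at 6.43 ± 0.20 (SD, n = 2) against 9.09 ± 0.01, and so was the cell cycle inhibitor gene Cdkn2a, at 7.93 ± 0.08 against 9.24 ± 0.03.

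Of 29 late and naive pluripotency genes 28 were higher in iPSC, adjusted over the list alone 28 (camera adjusted p = 3.45e-17, and adjusted p = 0.00186 with an estimated correlation). Of 20 early ones 19 were higher, adjusted over the list alone 19 (adjusted p = 2.77e-13, and adjusted p = 0.00825 with an estimated correlation). Of 30 germline genes 20 were higher, adjusted over the list alone 20, with the RNA-binding protein gene Dazl at 5.61 (adjusted p = 9.42e-10, and adjusted p = 0.0688 with an estimated correlation). DNA replication genes were higher in 24 of 29 cases, adjusted over the list alone 24, with Gins1 at 2.92 (adjusted p = 5.59e-15, and adjusted p = 0.0276 with an estimated correlation), and mitosis genes in 27 of 29, adjusted over the list alone 27, with Cenpf at 2.66 (adjusted p = 1.49e-15, and adjusted p = 0.0728 with an estimated correlation). Inflammatory genes were lower in 15 of 28 cases and higher in 1, adjusted over the list alone 15 and 1, with Il6 at -3.79 (adjusted p = 7.06e-07, and adjusted p = 0.0220 with an estimated correlation). Markers of macrophages and blood were lower too, in 13 of 23 cases, and higher in 1, adjusted over the list alone 13 and 1 (adjusted p = 3.05e-06, and adjusted p = 0.0688 with an estimated correlation). Among 19 genes of DNA methylation the list was not called (adjusted p = 0.103), while Dnmt3l stood at 5.98 and Tet1, which oxidises 5-methylcytosine, at 4.17. Polycomb and histone modifier genes were higher in 14 of 32 cases and lower in 1, adjusted over the list alone 14 and 1, with Cbx7 at 3.66 (adjusted p = 0.000168, and adjusted p = 0.143 with an estimated correlation). Genes induced by ERK signalling were lower in 15 of 20 cases, adjusted over the list alone 15, with the immediate early genes Egr1 and Fos at -3.53 and -3.23 (adjusted p = 1.10e-06, and adjusted p = 0.209 with an estimated correlation). That list was also lower on day 5, with 10 members lower and 1 higher, adjusted over the list alone 10 and 1 (adjusted p = 2.47e-05, and adjusted p = 0.282 with an estimated correlation). Of 30 fibroblast genes 22 were lower, adjusted over the list alone 23 (adjusted p = 1.85e-09, and adjusted p = 0.272 with an estimated correlation), and their mean against day 0 was -1.81 in iPSC and -3.60 on day 15. Among genes not called lower on day 15 than on day 0, a limit chosen after seeing the data, 2720 genes were called in iPSC against day 0. The limit by its construction removes genes that had fallen by day 15, so this count is not a test of the iPSC result.

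**Figure D4:**
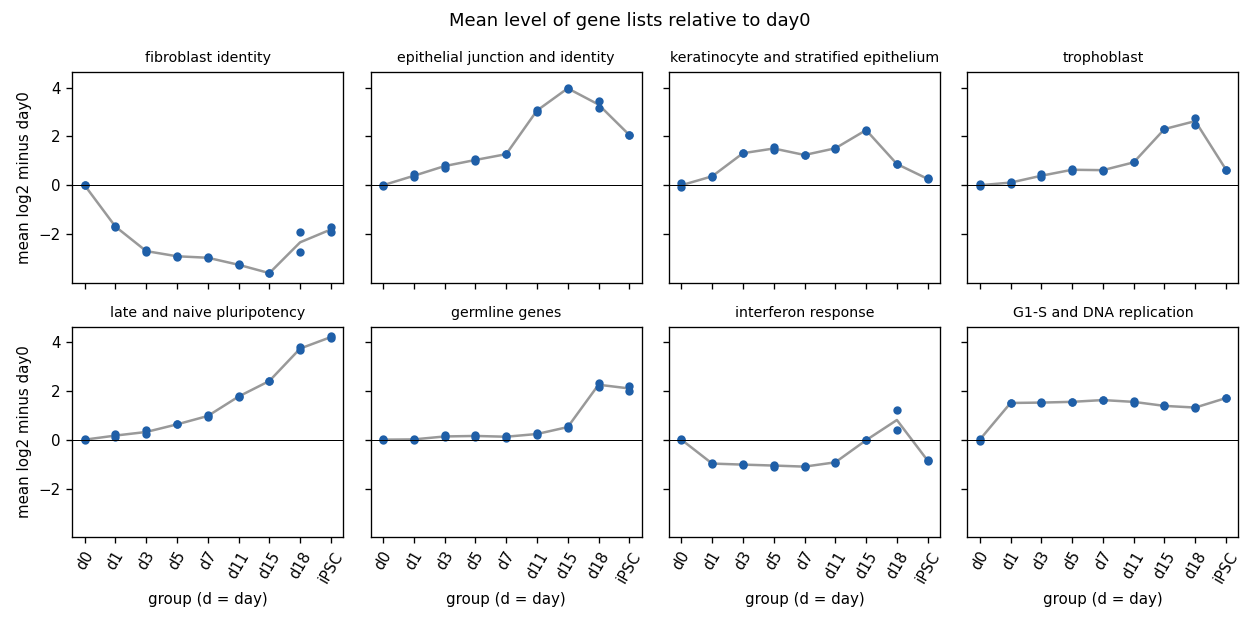
Mean log2 level of 8 gene lists in each array minus the day 0 mean (points) and the mean of the 2 arrays (line). The fibroblast list is lowest on day 15, at -3.60, and the interferon list lies at 1.20 and 0.41 in the arrays of day 18.

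On day 18, after the removal of doxycycline and vitamin C, germline and late pluripotency genes were higher than on day 15 and keratinocyte genes lower. No day 18 group kept the additives, so removal, the later day and the survival of only some cells cannot be told apart. The keratinocyte call was lost, with adjusted p = 0.0502 with an estimated correlation. The meiosis and germline genes Mael (4.53 ± 0.10, SE), Smc1b (4.31), Dazl (4.22), Meioc (4.19) and Sycp3 (4.07), the matrix genes Aspn (4.61) and Mmp3 (4.56), the Y-linked genes Eif2s3y (4.54) and Zfy1 (4.37) and Pramel19 (4.04) rose most. Ly6g6c (-5.11), Krtdap (-4.87), Ehf (-4.35), Clec2f (-4.15), Cyp4f39 (-4.10), the Fc receptor gene Fcgr2b (-4.04), the keratin gene Krt6a (-3.92), Aldh3a1 (-3.71), Shisa3 (-3.66) and Ahsg (-3.65) fell most. Myc fell too (-3.45). The lower level was under background for 9 of these 10 rises, the Y-linked genes among them, and for 4 of the 10 falls, which are lower bounds. Between the arrays of day 18 the SD of these genes ran from 0.01 to 1.39, the highest being that of Aspn, which stood 5.60 and 3.63 above day 15 in the 2 arrays. The SE of the model pools the spread over all groups, so it is too small for genes such as Aspn. There were 945 genes higher and 824 lower, and 1844 were called in all without day 18 replicate 1.

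Of 30 germline genes 20 rose on withdrawal, adjusted over the list alone 20, with Stra8, a gene of meiotic entry, at 3.79 (camera adjusted p = 1.87e-14, and adjusted p = 0.0272 with an estimated correlation). Late and naive pluripotency genes rose in 18 of 29 cases, adjusted over the list alone 18, with Dppa2 at 3.20 and Tcl1 at 2.82 (adjusted p = 1.50e-12, and adjusted p = 0.00671 with an estimated correlation). Keratinocyte genes fell in 13 of 24 cases and rose in 1, adjusted over the list alone 13 and 1, with Krt17 at -3.19 (adjusted p = 7.86e-07, and adjusted p = 0.0502 with an estimated correlation). Cholesterol biosynthesis genes fell as a list, with 2 of 24 called and 22 not, adjusted over the list alone 2, and Stard4 at -1.36 (adjusted p = 8.75e-07, and adjusted p = 0.0196 with an estimated correlation). Interferon response genes rose in 9 of 29 cases, adjusted over the list alone 9, with Ifit3 at 3.02 and an SD of 2.33 on day 18 (adjusted p = 1.15e-05, and adjusted p = 0.294 with an estimated correlation). Fibroblast genes rose in 17 of 30 cases, adjusted over the list alone 17, with Lox, the lysyl oxidase gene, at 3.50 and an SD of 0.51 on day 18 (adjusted p = 8.58e-11, and adjusted p = 0.267 with an estimated correlation). The interferon and fibroblast lists also differed between the 2 arrays of day 18, standing at 1.20 and 0.41 and at -1.93 and -2.74 against day 0.

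Genes called on induction were called in the opposite direction from day 15 to day 18 more often than in independent lists. The overlap cannot tell a reversal within cells from a change in which cells were present, such as more fibroblasts on day 18. Of the genes higher on day 1, 279 were lower on day 18 than on day 15, where 62.8 would be shared by independent lists (two-sided Fisher's exact test over 20233 genes, p = 1.25e-111), and of those lower on day 1, 296 were higher (61.8, p = 2.31e-127). The comparisons share no array. Genes are not independent replicates, and most of those 296 were still called lower on day 15 than on day 0, with more room to rise than to fall. The Fisher p-values therefore do not measure the evidence for a reversal. Over genes the log2 differences of the 2 comparisons correlated at r = -0.385, with the same limit. The first group held Tmprss11b, Fetub, Ceacam1, the alcohol dehydrogenase gene Adh7, the carbonic anhydrase gene Car12, Ctnnd2 and Bmp8b, with Ceacam1 at 10.08 on day 1, 11.47 on day 15 and 8.40 ± 0.05 (SD, n = 2) on day 18. The second held Aspn, Mmp13, Mmp3, Spp1, which encodes osteopontin, Igsf10 and Tgfbi. Of the second group 49 were left among genes not called lower on day 15 than on day 0, and of the first 278. That limit by its construction removes mainly genes of the second group, so the 2 counts are not a test of either overlap. Between the arrays of day 18 the SD of the named genes of the second group ran from 0.07 for Spp1 to 2.33 for Ifit3, with 1.65 for Casp12, 1.39 for Aspn and 0.64 for Igsf10.

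The iPSC line against day 18, which differ in medium as well as state, was lower in trophoblast, epithelial and interferon genes, calls that were lost with adjusted p = 0.0550, 0.0550 and 0.0824 with an estimated correlation. The largest falls were those of Serpinb9e (-6.25 ± 0.28, SE), Serpinb9f (-6.05), the trophoblast gene Tpbpa (-5.69), the placental prolactin family gene Prl2a1 (-5.62), the endothelial cadherin gene Cdh5 (-5.40), Fnd3c2 (-5.32), Krt8 (-5.26), Arhgef6 (-5.04) and Car4 (-5.04), with Gpr50 next. The matrix and muscle genes C1qtnf3 (4.03), Mfap4 (3.93), Postn (3.20), Tnmd (2.96) and Des (2.93), the oocyte genes Obox6 (3.58) and Nlrp4f (3.02), Crygd (3.67), Accsl (2.96) and Pappa (2.86) were higher in iPSC. For C1qtnf3, Mfap4 and Postn, feeder fibroblasts and the stem cells themselves were not told apart as the source. The lower level was under background for 4 of these rises and 9 of the falls, which are lower bounds, and the SD between the arrays of day 18 ran from 0.05 to 0.66. There were 317 genes higher and 575 lower, and 961 in all without day 18 replicate 1.

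Of 22 trophoblast genes 11 were lower in iPSC than on day 18, adjusted over the list alone 11, with Plac1 at -4.60 and Rhox9 at -4.22 (camera adjusted p = 8.25e-15, and adjusted p = 0.0550 with an estimated correlation). Epithelial genes were lower in 12 of 30 cases, adjusted over the list alone 12, with Krt18 and Krt19 at -4.18 and -4.14 (adjusted p = 6.69e-16, and adjusted p = 0.0550 with an estimated correlation). Interferon response genes were lower in 17 of 29, adjusted over the list alone 17, with Usp18 at -4.28 (adjusted p = 6.69e-16, and adjusted p = 0.0824 with an estimated correlation). ERK targets were lower in 7 of 20, adjusted over the list alone 7, with Fos at -2.97, Egr1 at -2.83 and the phosphatase gene Dusp6 at -1.99 (adjusted p = 3.64e-09, and adjusted p = 0.126 with an estimated correlation). Cholesterol biosynthesis genes were higher as a list, with 2 of 24 called and 22 not, adjusted over the list alone 2, and Pmvk at 1.05 (adjusted p = 4.60e-08, and adjusted p = 0.0295 with an estimated correlation). The list of totipotency genes of 2-cell-like cells, of which 8 of 20 were measured, rose, with 2 of 8 higher, adjusted over the list alone 2, and Zfp42 at 1.33 (adjusted p = 0.00224, and adjusted p = 0.0676 with an estimated correlation). Zfp42 is also among the pluripotency genes above, so this rise does not by itself show a 2-cell-like state.

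Many genes were highest or lowest in the intermediates. On at least 1 of days 1 to 15, 1367 genes were called higher than in both fibroblasts and iPSC and 963 lower. The steroid dehydrogenase family gene Akr1c18 stood at 11.20 ± 0.03 (SD, n = 2) on day 7, from 4.63 on day 0 and 4.75 in iPSC. Clec2f was at 9.61 on day 11 from 3.38 and 3.46, Spink12 at 9.93 on day 5 from 3.81 and 3.78, and Sprr1b at 10.79 on day 5 from 4.42 and 4.76. Krt8, Ly6g6c, Krt17 and Krtdap differed most from both ends on day 15 and Fndc3c1 on day 5. Krt8 stood at 12.43 ± 0.23 on day 18 as well. The transiently lower genes named by the rule were mostly matrix genes, which were not tested as a set: Aspn stood at 3.94 ± 0.07 on day 15, from 10.99 on day 0 and 10.48 in iPSC, and Postn, Lox, Ogn, Spp1, C1qtnf3, Mfap4, Cnn1, Loxl2 and Fmod were in the same group. Whether fibroblasts such as feeder cells or the stem cells themselves gave their iPSC levels was not told apart. Of the transiently lower genes 352 were among those not called lower on day 15 than on day 0, and 1102 higher and 708 lower genes also passed against day 18.

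The half-change day was compared between falling and rising genes without a test. Of 1981 genes lower in iPSC 51.5% had covered 0.5 of their change by day 1, and of 2038 genes higher 42.2%. The median day was 1 for the former and 3 for the latter, and 21.6% of the higher genes reached that point only on day 18. The median for higher genes was 5 when day 0 replicate 2 or day 1 replicate 2 was left out, and 11 with day 18 as the end of the course. The medians of both directions were 3 with equal array medians, with dim genes left out, with no minimum fold and with replicate 2 arrays alone, and both were 1 at a share of 0.25.

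Of 32 lists, camera with the preset correlation called 10 on day 1, 16 on day 3, 17 on day 5, 18 on day 7, 20 on day 11, 21 on day 15, 22 on day 18 and 21 in iPSC against day 0, 18 on withdrawal and 18 from day 18 to iPSC. With an estimated correlation the calls that held were those of inflammatory genes on days 5, 7, 11 and 15 and in iPSC, early and late pluripotency and DNA replication genes on days 11, 15 and 18 and in iPSC, macrophage genes on day 11, epithelial genes on days 15 and 18, keratinocyte genes on day 15 and germline genes on day 18. On withdrawal early and late pluripotency, germline and cholesterol genes held, and from day 18 to iPSC cholesterol genes.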

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

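All tests in this part were chosen after the results they bear on had been seen. Probe sets with no gene symbol took no part in the comparisons, and in the same limma model 185 of these 2383 were called higher in iPSC than in the day 0 fibroblasts and 82 lower. What they measure was not examined here.

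Fibroblast transcripts were lowest at day 15 and higher again afterwards. Of the 69 genes that had a log2 level of at least 10 in the fibroblasts and lost at least 4 by day 15, 60 lay at least 1 log2 above day 15 in iPSC and 57 at day 18. In the single arrays of day 18 it was 62 in replicate 1 and 41 in replicate 2. The olfactory receptor genes moved by a median of -0.0569 from day 15 to iPSC, against 2.02 for the fibroblast list. They lie near the floor of arrays that RMA had already background corrected and quantile normalized. Their array medians ran only from 3.44 to 3.69, so they had little room to rise and cannot decide on a higher background in iPSC. Scaling of brighter genes was not tested. Cells with the same profile as the day 0 fibroblasts are argued against as the whole source in iPSC, because the share of the day 0 level regained had a 75th percentile 5.74 times its 25th, and 5.53 times without Lyz2, a macrophage gene. The count of 60 restates the pattern and favours no source, so fibroblasts of another state, such as the feeder cells named in the labels, and expression by the stem cells themselves after the change of medium both stay open, because the design ties both to the same groups.

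Y-linked transcripts differed between days, and Eif2s3y stood at log2 4.24 ± 0.13 (SD, n = 2) on day 0, 3.99 ± 0.08 on day 15, 8.53 ± 0.01 on day 18 and 6.25 ± 0.14 in iPSC, and Ddx3y, Uty and Kdm5d were called higher on day 5 than on day 3 while Eif2s3y was at 4.49 ± 0.04. Xist stood at 5.01 ± 0.13 on day 0, 7.42 ± 0.41 on day 15, 6.45 ± 0.03 on day 18 and 8.53 ± 0.10 in iPSC. The levels of Eif2s3y on days 0, 5 and 15 lay under the background of 5.32. On day 0 Kdm5d (4.79) and Xist did too, while Ddx3y (5.77) and Uty (5.80) lay above it. On day 18 the olfactory receptor genes moved by a median of -0.117 from day 15 while the 4 Y-linked genes rose by a mean of 2.32. This cannot decide on a higher background, because RMA's background correction and quantile normalization leave genes near the floor little room to rise. Scaling of brighter genes was not tested. Carried-over cells like those of day 0 are argued against, since each of the 4 Y-linked genes stood at least 2.48 lower there than on day 18. That all 4 genes lay at least 1 log2 above day 0 on day 18 restates the pattern, so a larger share of Y-bearing cells there and expression raised in the same cells both stay open, and no test here bears on the levels of day 5. Whether all groups came from the same cells was not tested, and if they did not, every difference between groups would hold that difference too.

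The 2 arrays of day 18 differed more than those of any other group: 264 genes were over 2-fold apart, 252 of them higher in replicate 1, against 5 to 16 in the other groups. After another quantile normalization 249 stayed over 2-fold apart. The values had already been quantile normalized, so repeating that step cannot decide whether scaling plays a part. More fibroblasts in replicate 1 may account for a large part, because 65.1% of the genes higher there had been called lower on day 15 than on day 0, against 8.83% of all genes. That does not cover the interferon genes if the cells were like those of day 0, since the mean of the interferon list in replicate 1 lay 1.20 above its own day 0 level. The labels give no difference between the 2 arrays, and no biological explanation beyond these cell contents was tested.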

How the results depend on the processing

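The settings with day 18 as the end, without the day 5 arrays and with only genes not lower on day 15 were chosen after seeing the data, and the others before. A named gene counted as reversed if its sign changed and either fit called it, and a list only if both fits called it. Lists were not run with other fold limits, all probe sets or the trended and robust variance model. By these rules no named gene or list reversed its direction under the settings run. The balance of higher and lower genes against day 0 did: after another quantile normalization lower genes outnumbered higher ones on days 1, 7, 11, 15 and 18 and in iPSC, as 1397 to 1337 on day 1 and 2097 to 1948 in iPSC. With equal array medians this was so on days 15 and 18 and in iPSC, and higher genes outnumbered lower ones on days 3 and 5. The counts of called genes stayed within 1.5 times their reported value with another quantile normalization, equal array medians, dim genes left out, mean probe sets, the trended and robust variance model, only the 2 groups in the fit, and each array left out in turn. Under the estimated correlation 154 list calls were lost. With an array left out, 54 named-gene calls were lost and 59 gained, and 22 and 16 list calls, over all such fits together. Another quantile normalization lost 13 named-gene and 8 list calls and gained 16 and 3, and equal array medians lost 3 and 3 and gained 8 and 2. The mean of probe sets lost 3 and 1 and gained 2 and 1, leaving out dim genes lost 9 list calls and gained 4, and the trended and robust model lost 2 named-gene calls. The replicate numbers showed no pairing shared by all groups: the correlation of replicate differences over the 36 pairs of groups ran from -0.189 to 0.149 with 6 over 0.1. A batch shared by some groups is not excluded by this. With a replicate block 2865 genes were called on day 1, 893 in iPSC against day 18 and 15802 in the F test, and no named gene or list changed its side of the threshold. Where 1 array is left out, the lone array is assumed to vary like the other groups. Signal over background limits the 4897 genes under the 95th percentile of olfactory receptor genes in all groups, whose low values say little about absence.

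With no minimum fold change the calls against day 0 were 10123 on day 1, 11764 on day 3, 12123 on day 5, 11638 on day 7, 11418 on day 11, 11388 on day 15, 11665 on day 18 and 11694 in iPSC. Between neighbours they were 6581, 2986, 2430, 5229, 3281, 9455 and 7510, with 6731 genes transiently higher, 3825 transiently lower, and overlaps of 3056 and 1823. With a log2 difference of at least 2 the calls against day 0 were 518, 850, 1010, 1084, 1159, 1223, 1064 and 1086 in the same order, between neighbours 67, 28, 17, 85, 55, 332 and 211, with 337 and 213 transient genes and overlaps of 26 and 36. These follow from the limits themselves. Over all probe sets 5323 were called on day 18 and 6055 in iPSC against day 0, and 363 from day 3 to day 5, from more features tested. With only genes not lower on day 15 there were 352 transiently lower genes and an overlap of 49 between genes lower on day 1 and higher on withdrawal, because this limit removes genes called lower on day 15.

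With an estimated correlation the number of lists called was 0 on days 1 and 3, 1 on days 5 and 7, 5 on day 11, 6 on day 15, 5 on day 18 and 4 in iPSC against day 0, 4 from day 15 to day 18 and 1 from there to iPSC. The median half-change day of higher genes was 5 over all probe sets, 11 with a log2 difference of at least 2, 1 at a share of 0.25, 11 at 0.75 and 11 with day 18 as the end, and 3 to 5 with an array left out, being 5 without day 0 replicate 2 and without day 1 replicate 2. For lower genes it was 3 with equal array medians, with dim genes left out, with no minimum fold, at 0.75, and with replicate 2 arrays alone. The cause was not tested beyond the settings' construction.

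Some shares of the distance moved by more than the SD of their arrays. With dim genes left out they were 42.8, 55.1, 59.1, 63.0, 73.3 and 78.3% on days 1, 3, 5, 7, 11 and 15, with only genes called in iPSC 40.9, 52.2, 55.9, 59.7, 70.7 and 76.6%, and after another quantile normalization 42.4, 54.0, 71.8 and 76.5% on days 1, 3, 11 and 15. With 1 array left out they ran from 41.0 to 42.5% on day 1, 53.02 to 54.9% on day 3, 56.6 to 58.6% on day 5, 60.3 to 62.3% on day 7, 70.1 to 72.5% on day 11 and 74.7 to 77.6% on day 15.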

Other observations

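Lists of other lineages and processes were tested as well. Hox genes, which mark the position of fibroblasts in the body, fell in iPSC: 19 of 37 were called lower and 1 higher than on day 0, with Hoxd13 at -3.50 and Hoxd10 at -2.69 (camera adjusted p = 3.29e-06, and adjusted p = 0.162 with an estimated correlation). Adjusted over the list alone the counts were again 19 and 1. Markers of macrophages and blood fell by day 7, with 13 of 23 lower and the complement gene C1qb at -3.06 (adjusted p = 6.76e-07, and adjusted p = 0.0752 with an estimated correlation), and adjusted over the list alone there were 13. Glycolysis genes rose in iPSC, with 7 of 23 higher, adjusted over the list alone 7, among them the glucose transporter gene Slc2a3 at 5.04 and Aldoc at 3.33 (adjusted p = 1.10e-06, and adjusted p = 0.0688 with an estimated correlation). The unfolded protein response list fell by day 1, where 4 of 20 were lower, adjusted over the list alone 4, with Chac1 at -2.56 and Trib3 at -2.47 (adjusted p = 0.000435, and adjusted p = 0.0768 with an estimated correlation).

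Imprinted genes moved apart. On day 7, 10 of 25 were lower and 2 higher than on day 0, adjusted over the list alone 10 and 2: the growth factor gene Igf2 stood at -4.66 and Phlda2 at 3.66 (adjusted p = 0.00300, and adjusted p = 0.134 with an estimated correlation). Meg3, a noncoding RNA of the Dlk1-Dio3 cluster, was at log2 11.85 ± 0.00 (SD, n = 2) on day 0, 8.44 ± 0.04 on day 1, 10.45 ± 0.56 on day 18 and 11.53 ± 0.09 in iPSC, while Dlk1 of the same cluster stayed at 7.91 ± 0.13 in iPSC against 10.22 ± 0.05 on day 0. Neural genes were not called as a list on day 7 (adjusted p = 0.141), although 7 of 25 were higher and 4 lower, among the former the neurofilament gene Nefl at 4.15, Stmn2 at 3.86 and Pax6 at 3.59.

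The lists for mesoderm, WNT targets, skeletal and heart muscle and endothelium were not called between iPSC and day 0, with adjusted p = 0.486, 0.481, 0.162 and 0.428. Within the endothelial list Pecam1, a surface marker that mouse pluripotent cells also carry, stood at 4.95 and the factor gene Erg at -3.54, both lower bounds because the lower level was under background, as it was for Nefl, Pax6 and Cubn. The primitive endoderm list rose on withdrawal, with 5 of 25 higher, adjusted over the list alone 5, among them Cubn at 3.28 and Gata6 at 2.20 (adjusted p = 3.03e-05, and adjusted p = 0.0502 with an estimated correlation). Formative and primed pluripotency genes fell from day 18 to iPSC, with 3 of 20 lower, adjusted over the list alone 3, among them Otx2 at -1.69 and Dnmt3b at -1.33 (adjusted p = 0.00244, and adjusted p = 0.101 with an estimated correlation). Targets of p53 had adjusted p = 0.0321 in iPSC against day 0, with 6 of 25 lower and 2 higher, adjusted over the list alone 6 and 2 (adjusted p = 0.208 with an estimated correlation). Oxidative phosphorylation genes rose on day 1 as a list with 0 of 30 members called, adjusted over the list alone 0 (adjusted p = 0.000711, and adjusted p = 0.224 with an estimated correlation). The hypoxia list fell from day 18 to iPSC with 1 of 20 lower, adjusted over the list alone 1, the peptide hormone gene Adm at -1.09 (adjusted p = 0.000182, and adjusted p = 0.101 with an estimated correlation).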
